A study of Rattus norvegicus with 16 samples.

How the data were processed

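The series holds 16 one-colour arrays of total RNA from the renal outer medulla of male rats that were 5 weeks old at the start of dosing, per the labels' protocols. Cy3-labelled RNA was hybridised to a rat Agilent array, and spot intensity was extracted with Agilent Feature Extraction 10.7, per the submitters' processing notes. The deposited scanner files give for each spot the authors' processed signal intensity (background-subtracted on the linear scale), its median signal and local background, and other marks that flag spots as outliers, saturated or well above background, per the file headers. The authors' value table holds a ratio: its values matched the processed signal divided by the array's 75th percentile (r of log2 values at least 0.9999 on each array, column medians from 0.099 to 0.108), so its scale is linear and it is not centred by gene. The genome build of the array annotation was not needed, and no coordinates are given.

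From the deposited processed signal intensity, log2 values were taken and each array's 75th percentile was subtracted, over 61657 probes without controls. Spots marked as outliers (0 to 9 per array) were left out, and no spot was saturated. Probes were named by matching their RefSeq accession, without version, to a table of the GRCr8 assembly; 27460 probes of 15284 genes were named and 34197 were not, with 93.9% of NM accessions and 1.9% of XM accessions matched. Unnamed probes were tested apart: of 20652, 0 were higher and 1 lower at day 14, and 776 higher and 465 lower at day 28. The panel genes Top2a and Slc12a1 are not analysed here for want of a named probe. For each gene the probe with the highest mean over the 12 arrays was used, if well above background on all arrays of at least 1 of the 4 groups, leaving 11853 genes. Of 444 genes called at day 28 with several probes, 34 had another probe with the opposite sign.

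Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 12 arrays of days 14 and 28, with 1 mean per group, and p-values were adjusted by Benjamini-Hochberg over genes at a threshold of 0.05. Fold values are 2 to the power of the absolute log2 ratio, and errors are the model's SE. Gene list shifts were tested with camera at a preset correlation of 0.01, adjusted over 87 tests (29 lists and 3 contrasts), and repeated with the correlation estimated from the residuals; fry p-values are not used here. The lists name markers of nephron segments, of other cells of the kidney and blood, and of stress, damage and metabolic responses, and many of their genes are expressed by more than 1 tissue or cell type. For a gene that was well above background on no array of 1 group, a lower bound of the fold is given, the bright group's mean against, on each dim array, the higher of the lowest signal well above background and the probe's own signal. Days 1 and 7 have 1 pooled array per group. There the log2 ratio is given without a test. The median of a list is placed among the medians of 10000 random lists matched on expression in 20 bins. This place carries no spread between animals or tissue samples, and the random lists do not hold genes that vary together as list members may. The labels say that the arrays of days 14 and 28 come from separate animals.

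The samples, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per day, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap and that were well above background on all 6 arrays, up to 3 bounds per direction, the 8 largest log2 ratios of each direction in the pools, the 4 largest of each direction between vehicle groups, up to 4 passing members of each list, a fixed panel, and any list member as an example. Symbols that only number a locus were not named, and a few genes that the rule would name are not reported here. After the data were seen, genes of the vehicle comparison and list members that were not well above background on all 6 arrays were left out as well. Groups did not overlap for 18.1% of genes at day 14 and 32.8% at day 28, where chance gives 10%. Between the vehicle groups of day 28 and day 14 the share was 34.7%, so a share above 10% does not by itself point to treatment.

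The method was tested on simulated data made from the real means and spreads of 11844 genes. Noise was drawn independently per gene, with the same spread in all groups and without slide effects. The rates below therefore need not hold for the real arrays. Of genes changed by a log2 ratio of 1 in the day 14 comparison 79.6% were recovered, of those changed by 0.5 38.0%, and 5.08% of the calls were false; for the day 28 comparison the values were 79.6%, 38.4% and 3.92%. The alternatives were quantile normalization, scaling to the array median, normexp (offset 50) with quantile normalization, the authors' value table, other filters on dim probes, the mean of a gene's probes, fits of the 2 groups compared alone, a variance trend, a replicate block, slide as a fixed or random block, a 2-fold minimum and leaving out each array. The normexp alternative was planned on the mean spot signal and was run on the median spot signal. The glomerular marker score as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9.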

Results

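The outer medulla of the kidney was profiled in male Sprague-Dawley rats dosed daily by gavage with 2-amino-4-nitrophenol (ANP), a nitroaromatic compound of hair dyes, at 750 mg/kg/day, or with corn oil as the vehicle. RNA was measured on 16 one-colour Agilent arrays after 1, 7, 14 and 28 days. At days 1 and 7 each group had 1 array of RNA pooled from 3 animals, and at days 14 and 28 each group had 3 arrays, each of 1 animal. Between 64.75% and 69.6% of the probes were well above background on each array, the 75th percentile of the signal lay between 810 and 1324, and replicate arrays correlated across genes at r of 0.987 to 0.993. The number of arrays limits the precision. The design asks how the response of this kidney zone changes over the course of dosing, and each treated group was compared with the vehicle group of its own day.

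After 1 day the ANP pool had 794-fold more Havcr1 (kidney injury molecule 1) than the vehicle pool and 236-fold more Hmox1 (haem oxygenase 1), with log2 ratios of 9.63 and 7.88. Ugt2b7, a glucuronidating enzyme, was 188-fold higher, the aldo-keto reductase Akr1b8 59.9-fold, the stress transcription factor Atf3 51.0-fold, Zfand2a 31.3-fold, the mitochondrial uncoupling protein gene Ucp1 30.9-fold and Sdcbp2 29.4-fold higher. The largest decreases were those of Uvssa (541-fold), Gngt1 (20.9-fold), Stc2 (14.5-fold), the olfactory receptor genes Or2n1e and Or2n1el1 (both at least 10.6-fold), Or6c3b (9.77-fold) and Or2n1j (9.20-fold), and Creb3l3 (8.01-fold), a transcription factor of lipid metabolism. Uvssa stood at 6.24 on the log2 scale in the vehicle pool of day 1 alone, against -2.84 in the ANP pool and -2.68 in the vehicle pool of day 7. Of 12468 genes, 623 were at least 2-fold higher and 641 at least 2-fold lower. These values come from 1 array per group, so no test was possible and the ratios carry no error.

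Several gene lists fixed in advance stood apart from random lists of like size and expression at day 1. Tubular injury and repair markers had a median log2 ratio of 1.72, with 19 of 22 members above 0, among them Lcn2 at 2.77, Cd44 at 2.67, Spp1 (osteopontin) at 2.01, Timp1 at 1.93 and Clu (clusterin) at 1.38. Immediate early genes had a median of 1.47 and all 15 were above 0, with Fos at 3.89 and Myc at 2.53. Heat shock genes had a median of 1.46 and all 11 were above 0, led by Hspa1a at 4.83. Chemokines, cytokines and adhesion genes had a median of 1.37, with Cxcl1 at 4.28 and Ccl2 at 2.70. NRF2 target genes, which serve antioxidant defence, had a median of 1.28, with Slc7a11 at 4.42, Abcc2 at 4.17, Srxn1 at 4.15 and Nqo1 at 3.73, while Gclc (-0.51) and Gclm (-0.20), the subunits of the enzyme that starts glutathione synthesis, were not among the higher members. Cholesterol biosynthesis genes (median 0.68), ATF4 and unfolded protein response genes (0.58; Trib3 at 3.48, Gdf15 at 3.38) and p53 target genes (0.58; Plk2 at 1.88, but Cdkn1a at -0.19) also lay above all 10000 random lists. Below all 10000 random lists were the straight proximal tubule (S3) markers, with a median of -0.998 and 17 of 18 below 0, and fatty acid oxidation genes, with a median of -0.82 and 23 of 23 below 0. The organic anion transporter Slc22a7 was at -2.60 and the cystine and aspartate transporter Slc7a13 at -1.20.

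Other lists at day 1 were nearer to 0. The medians were 0.45 for inner medulla and thin limb markers, 0.37 for apoptosis and necroptosis genes, 0.20 for hypoxia and glycolysis genes, 0.21 for cell cycle genes and 0.19 for extracellular matrix and fibrosis genes, which 9, 8, 95, 180 and 240 of the 10000 random lists reached. On the lower side, interferon response genes (-0.47), convoluted proximal tubule (S1/S2, cortex) markers (-0.44), xenobiotic phase I and II enzyme genes (-0.36) and oxidative phosphorylation genes (-0.31, 20 of 20 below 0) were matched by 4, 14, 32 and 288 random lists. The medians of the thick ascending limb, collecting duct, glomerular, endothelial, macrophage and myeloid, lymphocyte, complement, metallothionein and iron handling, haemoglobin and erythroid, and adipocyte lists lay between -0.34 and 0.19, at percentiles of 5.5 to 91.7.

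At day 7 the ANP pool had 41.2-fold more Akr1b8, 23.7-fold more Hmox1, 20.4-fold more Ugt2b7, 18.7-fold more Havcr1 and 12.6-fold more Abcc2, an export pump of glutathione and glucuronide conjugates, than its vehicle pool. Pir (9.64-fold), Ugt2b37 (9.62-fold) and Ugt2b15 (9.55-fold) followed. Cyp2c11, a cytochrome P450 typical of male rats, was 32.6-fold lower, and Shisa3 (9.61-fold), Anxa13 (8.72-fold), Gtpbp4 (8.38-fold), Or6c3b (6.96-fold), Or5b95 (6.84-fold), Or2n1e (6.73-fold) and Nsg1 (6.15-fold) were also lower. NRF2 target genes had a median of 1.16 with 19 of 21 above 0, and xenobiotic phase I and II enzyme genes (0.36) and convoluted proximal tubule markers (0.44, 15 of 16 above 0) also lay above all 10000 random lists. Injury and repair markers had a median of 0.25, which 4 random lists reached, with Clu at 1.21 beside Spp1 at -0.34 and Lcn2 at -0.12. Of the lists that were high at day 1, heat shock (0.27), p53 target (0.20), cholesterol biosynthesis (0.16) and ATF4 genes (0.15) were nearer to 0, and immediate early genes (0.10) and chemokines (0.01) lay at percentiles of 82.0 and 41.7. Inner medulla and thin limb (-0.61), macrophage and myeloid (-0.49), interferon response (-0.47) and thick ascending limb (-0.34) medians lay below all 10000 random lists. A difference between the pools in the tissue sampled was not tested.

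The remaining day 7 medians were -0.39 for adipocyte genes, -0.30 for endothelial, -0.28 for collecting duct, -0.27 for extracellular matrix, -0.23 for complement, -0.18 for haemoglobin, -0.15 for cell cycle and -0.11 for straight proximal tubule lists, each matched by between 1 and 130 of the random lists, and 0.20 for metallothionein and iron handling genes, matched by 202. Glomerular, lymphocyte, fatty acid oxidation, oxidative phosphorylation, hypoxia and glycolysis, and apoptosis medians lay between -0.24 and 0.09. Of 12188 genes, 282 were at least 2-fold higher and 343 at least 2-fold lower, and 146 and 174 when a gene had to be well above background on both arrays. Across 11561 genes, which are not independent replicates, the log2 ratios of day 1 and day 7 correlated at r = 0.26 (Spearman's rho 0.13), and no difference between these days was tested.

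**Figure D1:**
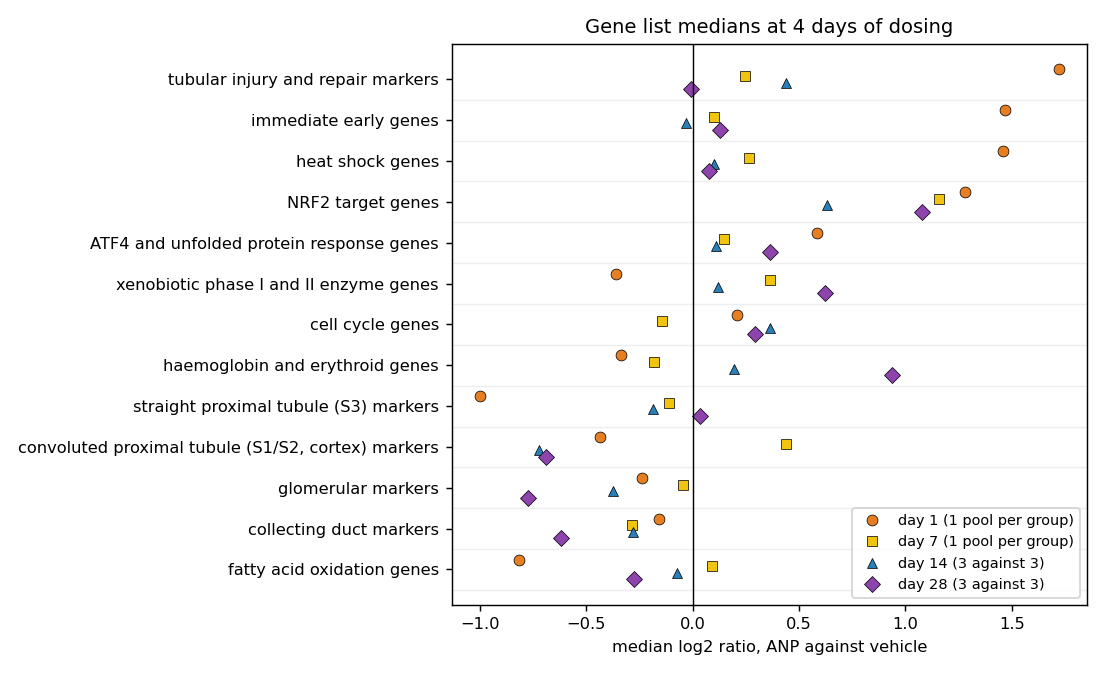
Median log2 ratio (ANP against vehicle of the same day, horizontal axis) of 13 gene lists at days 1, 7, 14 and 28, with 1 symbol per day and the line at 0 marking no difference. NRF2 target genes lie above 0 at every day, at 1.28, 1.16, 0.63 and 1.08, while injury and repair markers go from 1.72 at day 1 to -0.01 at day 28.

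At day 14, 43 genes rose and 14 fell with ANP among 11853 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Ptgr1, a reductase of prostaglandins and reactive alkenals, rose 6.18-fold (log2 ratio 2.63 ± 0.37, SE, n = 3 per group; limma adjusted p = 0.02), and Pir, an iron-binding nuclear protein gene, rose 4.88-fold (2.29 ± 0.40; limma adjusted p = 0.0445). Gjb5, a connexin, rose 6.23-fold, the phosphatase Ppm1j 5.16-fold, the GABA-B receptor subunit gene Gabbr2 4.95-fold, Gpr15lg 3.59-fold, Stra6l 3.46-fold, asparagine synthetase Asns 3.23-fold, Ankrd34b 3.13-fold and the lipid droplet gene Cidea 3.11-fold. Gas2 fell 4.36-fold (log2 ratio -2.13 ± 0.19; limma adjusted p = 0.00406), the neurofilament gene Nefm 4.33-fold, the receptor kinase gene Ros1 2.99-fold, the beta-defensin Defb42 2.96-fold, Ppfia4 2.92-fold, AKR1C3l1 2.41-fold, Sorcs1 2.14-fold, Entrep3 2.10-fold, the chemokine Cxcl11 1.99-fold and Sarnp 1.72-fold. Of genes not well above background in 1 group, Lyzl1 was at least 6.34-fold, Shcbp1l at least 3.87-fold and Ccn5 at least 3.08-fold higher. On the same terms Qrfpr was at least 3.16-fold and Paep at least 2.19-fold lower (limma adjusted p from 0.00651 to 0.0411 over these 5 genes). Cyp2c11 was at -6.70 ± 1.26 and did not pass (limma adjusted p = 0.0532).

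By camera with a preset correlation, 10 gene lists were called at day 14. None of these calls held when the correlation was estimated (adjusted p = 0.727 with an estimated correlation for each). Hypoxia and glycolysis genes, not called at day 14 (camera adjusted p = 0.277), had the same 0.727. Their estimated correlation was 0.00254, below the preset one. The value of 0.727 therefore did not tell called lists from others. Its repeats below do not rank the lists. The estimated correlations of the 10 called lists ran from 0.046 to 0.653, above the preset 0.01 on which the calls rest, so the calls stay uncertain. NRF2 target genes had a median log2 ratio of 0.63 (camera adjusted p = 5.03e-06; adjusted p = 0.727 with an estimated correlation). Akr7a3 rose 1.81-fold, the other 19 members did not pass, and 7 passed when adjusted over the list alone. Nqo1 was at 2.62 ± 0.53 (limma adjusted p = 0.0662) and Hmox1 at 2.97 ± 0.91 (limma adjusted p = 0.199). Cell cycle genes had a median of 0.37 with 21 of 22 above 0 (camera adjusted p = 3.83e-05; adjusted p = 0.727 with an estimated correlation), no member passed, and 3 did when adjusted over the list alone. Injury and repair markers had a median of 0.44 (camera adjusted p = 0.00094, and 0.727 with an estimated correlation). Gpnmb rose 2.93-fold, while 6 passed when adjusted over the list alone. Against the vehicle mean, the list medians of ANP replicates 1, 2 and 3 were 0.078, 0.881 and 0.186, so the shift was uneven among the animals. Clu was 2.14-fold higher (SE 0.21 on the log2 scale; limma adjusted p = 0.0531) and Havcr1 at 2.10 ± 0.54 (limma adjusted p = 0.135). The p53 target genes had a median of 0.21 (camera adjusted p = 0.0178; adjusted p = 0.727 with an estimated correlation; 3 members adjusted over the list alone), with Cdkn1a at -0.03 and Mdm2 at 0.18. Heat shock genes had a median of 0.10 (camera adjusted p = 0.0466; adjusted p = 0.727 with an estimated correlation), Hspb8 rose 2.53-fold, and 1 passed when adjusted over the list alone. The median of the heat shock genes at day 14 turned to -0.0189 without vehicle replicate 3 and was 0.281 without vehicle replicate 1.

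Markers of the renal cortex had medians below 0 in the same samples. Glomerular markers had a median of -0.37 with 12 of 14 below 0 (camera adjusted p = 0.000435; adjusted p = 0.727 with an estimated correlation) and convoluted proximal tubule markers one of -0.73 with 14 of 16 below 0 (camera adjusted p = 0.00071; adjusted p = 0.727 with an estimated correlation). The convoluted tubule scores of the vehicle arrays were 0.29, -0.53 and -1.12 and those of the ANP arrays -0.80, -1.10 and -1.12, so vehicle replicate 3 was as low as ANP. Without vehicle replicate 1 the median of the convoluted proximal tubule markers at day 14 was -0.33 and the list was not called (camera adjusted p = 0.0997). No member of either list passed over all genes, and adjusted over the list alone 3 glomerular genes were lower, and 3 convoluted tubule genes lower and 2 higher. The glucose transporter Slc5a2 was at -1.03, while the urate transporter Slc22a12 was at 0.66. Straight proximal tubule markers (median -0.19; camera adjusted p = 0.00151), collecting duct markers (-0.28; camera adjusted p = 0.0157) and fatty acid oxidation genes (-0.08; camera adjusted p = 0.0359) were also called lower (adjusted p = 0.727 with an estimated correlation for each), with no member passing over all genes or when adjusted over the list alone.

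The other 19 lists were not called at day 14, with camera adjusted p from 0.0691 for lymphocyte markers to 0.898 for oxidative phosphorylation genes and medians from -0.19 to 0.19. In them Asns was the only gene that passed over all genes. Adjusted over the list alone, 5 xenobiotic enzyme genes were higher and 1 lower, 2 immediate early and 2 hypoxia genes higher with 1 lower in each, 2 ATF4 genes higher and 1 apoptosis gene lower. The median and the mean differed in sign for immediate early genes (-0.03 and 0.24), macrophage markers (-0.05 and 0.06) and thick ascending limb markers (-0.01 and 0.01), and the test followed the mean except for macrophage markers. The vehicle arrays and ANP replicate 1 shared a slide while ANP replicates 2 and 3 lay on another. With slide as a block, which leaves ANP replicate 1 against the 3 vehicle arrays, no gene passed (limma, smallest adjusted p = 0.157). With 1 ANP array and the spread taken from the other groups a loss of calls was close to given, and the log2 ratios there were -2.17 for Gas2, 2.65 for Gjb5, 2.11 for Ptgr1 and 1.30 for Asns. The list medians were 0.67 for NRF2 targets, 0.29 for cell cycle, 0.18 for p53 targets, 0.10 for heat shock, and 0.08 for injury markers. On the lower side they were -0.42 for glomerular, -0.41 for convoluted tubule, -0.35 for collecting duct, -0.03 for straight tubule and -0.04 for fatty acid oxidation genes. The counts of 43 and 14 fell to 0 and 1 without ANP replicate 3, to 3 and 4 without ANP replicate 2 and to 2 and 1 without vehicle replicate 2.

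At day 28, 530 genes rose and 312 fell with ANP among the same 11853 (limma, adjusted p under 0.05). Akr1b8 rose 35.4-fold (log2 ratio 5.14 ± 1.12, SE, n = 3 per group; limma adjusted p = 0.0267), the glutathione transferase Gstm1 20-fold (4.32 ± 0.73; limma adjusted p = 0.0112), the quinone reductase Nqo1 13.0-fold (3.70 ± 0.53; limma adjusted p = 0.00705) and Asns 11.1-fold (3.47 ± 0.30; limma adjusted p = 0.00184). The growth factor gene Areg (amphiregulin) rose 11.7-fold, the stress gene Nupr1 8.68-fold, Pycr1 of proline synthesis 7.72-fold, the tight junction gene Cldn14 6.65-fold, Mthfd2 of mitochondrial folate metabolism 6.52-fold and Pir 6.48-fold. Cyp2c11 fell 65.3-fold (-6.03 ± 1.26; limma adjusted p = 0.0232), with an SD of 3.03 among the vehicle arrays, where replicate 3 was at -2.13 and the others at 2.45 and 3.59. The vitamin D carrier Gc fell 6.32-fold, Creb3l3 4.39-fold, Mylk3 7.34-fold, Cntnap4 4.93-fold, Defb42 4.08-fold, Colq 3.89-fold, the podocyte phosphatase gene Ptprq 3.73-fold and the GDNF receptor Gfra1 3.68-fold. Gjb5 was at least 11-fold, Lyzl1 at least 8.74-fold and Csmd1 at least 6.24-fold higher, and Defb21 at least 8.08-fold, Dnajc5b at least 2.5-fold and Tbx4 at least 2.42-fold lower, against a group where each was not well above background (limma adjusted p from 0.00301 to 0.0365).

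Of the NRF2 target genes 11 of 20 rose at day 28 and 9 did not pass. All 20 were above 0 and 15 passed when adjusted over the list alone, with a median log2 ratio of 1.08 (camera adjusted p = 1.1e-09; adjusted p = 0.727 with an estimated correlation). Beside Nqo1, Abcc2 rose 4.44-fold, Srxn1 4.38-fold and Gclm 3.30-fold, while Hmox1 was at 1.71 ± 0.91 (limma adjusted p = 0.256). Xenobiotic enzyme genes had a median of 0.62 (camera adjusted p = 0.0227; adjusted p = 0.727 with an estimated correlation), and 6 of 19 rose. The same number rose when adjusted over the list alone, and 1 was lower. Gstm2 rose 2.47-fold, Mgst1 2.09-fold and Ugt1a6 1.81-fold. Of the ATF4 and unfolded protein response genes 7 of 22 rose, with a median of 0.36 (camera adjusted p = 0.00161; adjusted p = 0.727 with an estimated correlation; adjusted over the list alone 9 higher and 1 lower). Beside Asns and Mthfd2, Trib3 rose 4.18-fold and Gdf15 1.76-fold. The chaperone Hspa5 was at -0.18 and the chaperone Pdia4 at -0.60 (limma adjusted p = 0.508 and 0.0702). Haemoglobin and erythroid genes had a median of 0.94 and 5 of 9 rose (camera adjusted p = 0.000435; adjusted p = 0.727 with an estimated correlation; 6 adjusted over the list alone). These were Ahsp 4.03-fold, Alas2, the haem synthesis enzyme of red cell precursors, 3.10-fold, Hbb 1.91-fold, Hba-a1 1.81-fold and Bpgm. Cell cycle genes had a median of 0.29 (camera adjusted p = 0.0271; adjusted p = 0.824 with an estimated correlation), with Birc5 (1.77-fold) the 1 member that rose, also when adjusted over the list alone.

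Several cortical and collecting duct markers fell at day 28 in the same samples, while most members of these lists did not pass. Glomerular markers had a median of -0.78 (camera adjusted p = 0.000396; adjusted p = 0.727 with an estimated correlation), and 4 of 14 fell (6 adjusted over the list alone), among them Ptpro 1.99-fold, Clic5 1.73-fold and Podxl 1.70-fold. Convoluted proximal tubule markers had a median of -0.69 (camera adjusted p = 0.00282; adjusted p = 0.813 with an estimated correlation), and their members went both ways. Slc7a8 fell 2.84-fold and the endocytic receptor Lrp2 1.64-fold, while the transporters Slc17a1 and Slc22a12 rose 2.28-fold and 1.80-fold (8 lower and 2 higher adjusted over the list alone). Collecting duct markers had a median of -0.62 (camera adjusted p = 0.000251; adjusted p = 0.727 with an estimated correlation), and 5 of 15 fell (8 adjusted over the list alone). They were Hsd11b2, which inactivates corticosterone, 2.09-fold, Gata3 1.70-fold, the sodium channel subunit Scnn1g 1.64-fold and the proton pump subunits Atp6v1b1 (1.54-fold) and Atp6v1g3. Fatty acid oxidation genes had a median of -0.28 (camera adjusted p = 0.000581; adjusted p = 0.727 with an estimated correlation), and 2 of 23 fell (4 adjusted over the list alone), among them Eci1, an isomerase of unsaturated fatty acids, 1.65-fold. Lymphocyte markers had a median of -0.36 (camera adjusted p = 0.0111; adjusted p = 0.727 with an estimated correlation) with no member passing in either way.

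The other 19 lists were not called at day 28, with camera adjusted p from 0.0797 for thick ascending limb markers to 0.995 for adipocyte genes and medians from -0.19 to 0.27. Injury and repair markers had a median of -0.01 and a mean of 0.03, with the test pointing down. Anxa2 rose 1.70-fold, Havcr1 was at -0.03 ± 0.54 and Clu at -0.22 ± 0.21. Straight proximal tubule markers had a median of 0.03 and a mean of -0.02, with the test pointing up. Slc22a7 rose 3.20-fold and Mep1b 1.53-fold, and Slc7a13 was at 0.15. Metallothionein and iron handling genes had a median of 0.10 and a mean of -0.14, with the test pointing down, and Tfrc rose 1.33-fold. Among the rest, Hspb8 (2.09-fold) and Cryab (1.60-fold) of the heat shock genes and Egln3 (2.00-fold) and Bnip3 (1.92-fold) of the hypoxia genes rose. The endothelial receptor Kdr (1.43-fold) and the complement gene C4a (2.18-fold) fell. Umod, the main thick limb transcript, was at 0.21, Aqp2 at -0.22 and Cdkn1a at 0.20. The 3 ANP arrays of day 28 lay on a slide and scan day of their own, so slide and treatment cannot be told apart there. Without vehicle replicate 2 the counts of 530 and 312 became 148 and 60, without vehicle replicate 1 144 and 68, and scaling to the array median gave 773 and 244.

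**Figure D2:**
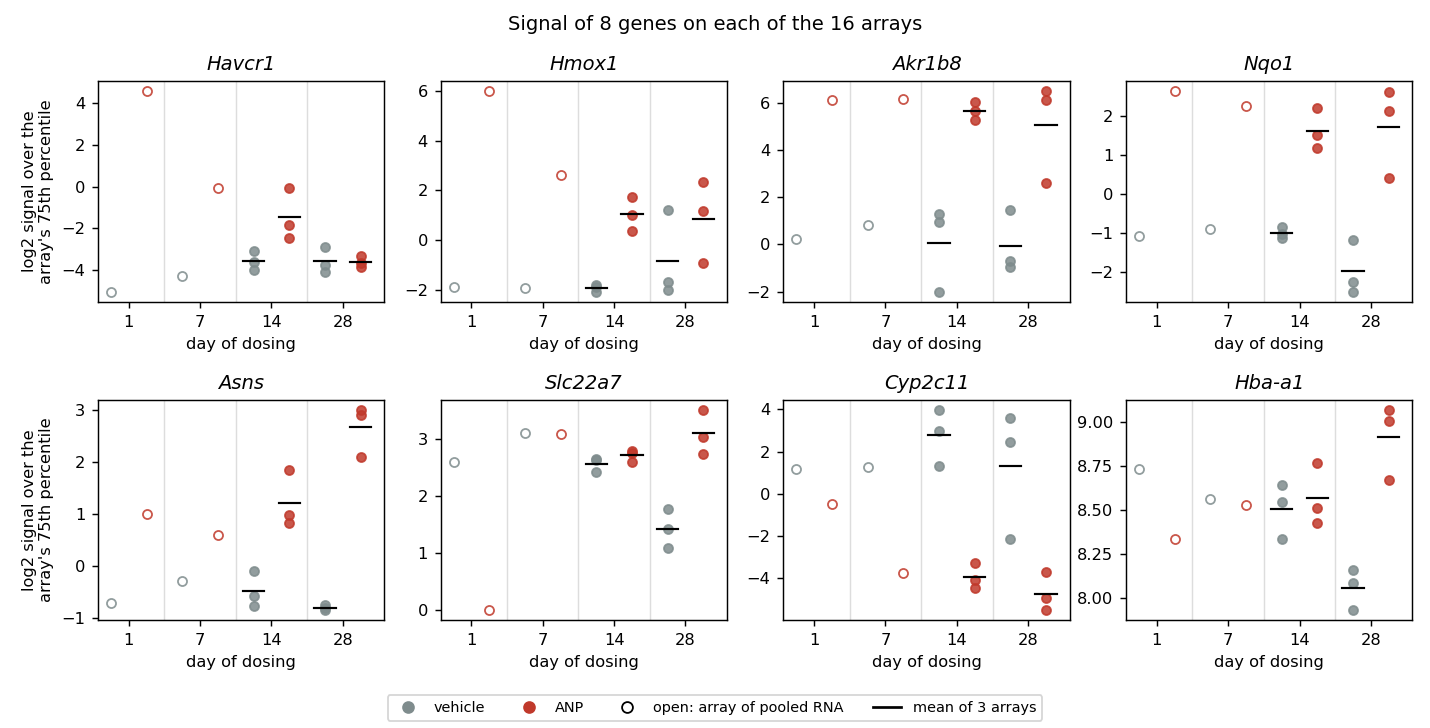
Log2 signal of 8 genes relative to the 75th percentile of each array (vertical axes) by day of dosing, vehicle in grey and ANP in red, with open points for pooled arrays and lines for means of 3 arrays. Havcr1 with ANP stands at 4.59 at day 1 and at a mean of -3.60 at day 28, where vehicle is at -3.57, while Asns with ANP reaches a mean of 2.66 at day 28 against -0.81 with vehicle.

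The responses of day 14 and day 28 were then set against each other. No gene passed the test of the difference between the log2 ratios (limma; smallest adjusted p = 0.252), and 1098 genes (9.26%) had an unadjusted p under 0.05. Of the 43 genes higher at day 14, 34 were also called higher at day 28, where 1.92 would be shared by independent lists. Of the 14 lower genes, 10 were called lower at day 28, against 0.369. Both comparisons used 1 estimate of the spread per gene, which favours the same genes at both days, so independent lists are a low baseline. By camera, with an adjusted p = 0.727 with an estimated correlation for each list named here, the shift at day 28 was above that at day 14 for haemoglobin and erythroid genes (median difference 0.79; adjusted p = 0.000581), NRF2 targets (0.37; adjusted p = 0.00192), straight proximal tubule markers (0.31; adjusted p = 0.00518) and ATF4 genes (0.24; adjusted p = 0.00747). It was below that at day 14 for injury and repair markers (-0.31; adjusted p = 0.00257), collecting duct markers (-0.33; adjusted p = 0.00842) and fatty acid oxidation genes (-0.18; adjusted p = 0.0424), again with an adjusted p = 0.727 with an estimated correlation for each. No member passed over all genes, and adjusted over the list alone 1 haemoglobin, 2 NRF2, 2 straight tubule and 4 ATF4 genes were higher and 2 injury genes and 1 collecting duct gene lower. The other 22 lists were not called, with adjusted p from 0.185 to 0.849, and only hypoxia and glycolysis genes had a median (-0.00034) and a mean (0.04) of opposite sign.

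The genes called at days 14 and 28 were also read in the pooled arrays, which had controls of their own. Of the genes higher at day 14, 41 of 43 lay above 0 at day 7 (95.3%, against 56.2% of all genes) and 33 of 42 at day 1 (78.6%, against 46.0%). Of those higher at day 28, 450 of 529 lay above 0 at day 7 (85.1%) and 328 of 528 at day 1 (62.1%). Of those lower at day 28, 176 of 309 lay below 0 at day 7 (57.0%, against 43.8% of all genes) and 216 of 309 at day 1 (69.9%, against 54.0%). Across genes, the log2 ratios of day 14 correlated with those of day 28 at r = 0.566, of day 1 at 0.369 and of day 7 at 0.357.

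Vehicle animals of day 28 and day 14 were compared as a control without treatment. Between them 832 genes were higher and 495 lower at day 28 (limma, adjusted p under 0.05). The kallikrein genes Klk1b3, Klk1 and Klk1c2 were 15.6-fold, 14.9-fold and 14.9-fold higher, with SDs of 2.09 to 2.23 on the log2 scale among the day 14 arrays. Cldn14 was 8.06-fold lower. Convoluted proximal tubule markers had a median of 1.53 and 10 of 16 were higher, glomerular markers a median of 0.85 and 7 of 14 were higher, and inner medulla and thin limb markers a median of -0.61 and 2 of 11 were lower. Cell cycle genes had a median of -0.78, with 8 of 22 lower and 1 higher. These vehicle groups lay on different slides of the same scan day, so age, slide and the tissue sampled cannot be told apart, and without vehicle day 28 replicate 2 the total of 1327 genes became 430.

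**Figure D3:**
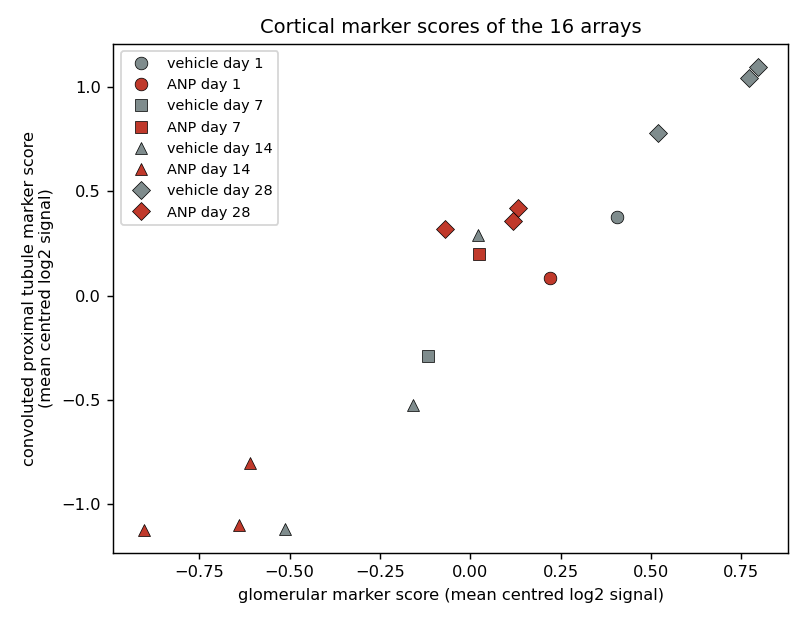
Glomerular marker score (horizontal) against convoluted proximal tubule marker score (vertical), each the mean centred log2 signal of the list, for the 16 arrays, with colour for treatment and symbol for day. The 3 vehicle arrays of day 28 lie at glomerular scores of 0.52 to 0.80 and the 3 ANP arrays of that day at -0.07 to 0.13, while the 3 vehicle arrays of day 14 spread from -0.51 to 0.02.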

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

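The tests on distal tubule, neutrophil and platelet, and reticulocyte genes, and those on single arrays and slides, were chosen after the patterns below had been seen but before their own values were computed, and the neutrophil and platelet list was first run with 1 member left out in error, which gave the same reading as the list as written.

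Glomerular and convoluted proximal tubule markers had medians below 0 with ANP at days 14 and 28, with no called difference between the days. In the pools the convoluted tubule median was -0.435 at day 1 but 0.44 at day 7, and the glomerular median -0.239 and -0.0471. On the slide that the vehicle arrays of day 14 share with ANP, the median over both lists was -0.414 (95% interval over members -0.594 to -0.286), which met the bound set beforehand against the slide, but that bound took its spread over genes of 1 ANP array, so the slide at day 14 stays open. The glomerular score of this array, replicate 1, was -0.61, below all 3 vehicle arrays (-0.51 to 0.02), and its convoluted tubule score was -0.80, within the vehicle range (-1.12 to 0.29). Less cortical tissue in the ANP samples would also lower distal convoluted and connecting tubule genes. Their medians were -0.487 (interval over members -1.12 to -0.0937) at day 14 and -0.916 (-1.40 to -0.379) at day 28. These intervals hold no spread between animals, and at day 14 no member passed. A difference in the share of cortex may account for part of these shifts, which stays open. An effect of ANP on cortical cells stays open as well, since Slc17a1 and Slc22a12 rose while other markers of the same segment fell, and at day 28 the slide cannot be told apart from treatment.

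Haemoglobin and erythroid genes had a larger log2 ratio at day 28 than at day 14, with a median difference of 0.791 (adjusted p = 0.727 with an estimated correlation). Neutrophil and platelet genes had a median of 0.0418 at day 28 (interval over members -0.0758 to 0.355), against 0.936 for the haemoglobin list. This met the bound set beforehand against more whole blood in the samples. The interval holds no spread between animals, and Lcn2 of this list is also an injury marker, so more whole blood stays open. A larger share of young red cells may contribute, since reticulocyte genes outside the list had a median of 0.349 (interval over members 0.131 to 1.25). Of these genes 3 of 13 passed the test, among them Rhd and Klf1 (log2 ratios 2.10 and 1.25). More blood could raise reticulocyte genes too, so they do not tell the 2 explanations apart. At day 28 the slide cannot be told apart from treatment. The median of the haemoglobin list was -0.378 between vehicle day 28 and vehicle day 14, with 0 of 9 members passing, and the scores of the vehicle arrays were -0.90, -0.33 and -0.33 at day 28 and -0.49, 0.33 and -0.11 at day 14.

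Injury and repair markers had a smaller log2 ratio at day 28 than at day 14, with a median difference of -0.311 (adjusted p = 0.727 with an estimated correlation). Against the vehicle mean, the list medians of the 3 ANP arrays of day 14 were 0.078, 0.881 and 0.186, so the shift may rest largely on 1 animal, replicate 2. On the slide shared with the vehicle arrays the median was 0.078 (interval over members -0.128 to 0.191), but this is the value of ANP replicate 1 alone. Replicates 2 and 3 lay on the same other slide at 0.881 and 0.186, so the slide alone does not give the high value of replicate 2. A smaller part of the slide stays open. A fall of these markers with longer dosing is the biological explanation that the design gives, and it stays open.

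The difference between the day 28 and day 14 shifts was also called by camera for straight proximal tubule (S3) markers, with a median of 0.313. For this list and the 4 that follow, no member passed and the call was lost (adjusted p = 0.727 with an estimated correlation). Xenobiotic phase I and II enzyme genes, not called for this difference (camera adjusted p = 0.191), had the same 0.727. The tied value therefore does not rank these lists. Their estimated correlations, from 0.162 to 0.389, lay above the preset 0.01 on which the calls rest, so the calls stay uncertain. Collecting duct markers had a median difference of -0.331. NRF2 target genes had a median difference of 0.37. ATF4 and unfolded protein response genes had a median difference of 0.238. Fatty acid oxidation genes had a median difference of -0.184. Between vehicle day 28 and vehicle day 14 the medians were -0.344 for straight proximal tubule and 0.417 for collecting duct markers. They were 0.314 for fatty acid oxidation, -0.0899 for NRF2 target and 0.0226 for ATF4 genes. The differences of the straight tubule, collecting duct and fatty acid oxidation lists may therefore lie partly on the vehicle side. In vehicle at day 28, 3 of 20 NRF2 targets were lower and 0 higher, and 5 of 22 ATF4 genes were higher and 0 lower. A vehicle part is therefore not excluded for single members of these 2 lists. Groups of 3 arrays were not searched for outlying samples.

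Splits of 3 against 3 arrays number 10, which is too few for a share under 0.05. The real split gave 57 genes at day 14, where the highest of the others gave 0. It gave 842 genes at day 28, where the highest of the others gave 1. It gave 1327 genes between the vehicle groups, where the highest of the others gave 0. Every other split mixes the real groups, which moves any difference between them, whatever its cause, into the spread. Low counts there were therefore close to given, and they do not tell treatment from slide, age or the tissue sampled.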

How the results depend on the processing

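The 1 setting chosen after seeing the data is the glomerular marker score as a covariate, and unless a value shows otherwise the cause of a change was not tested. Genes higher and lower at day 14 (43 and 14) numbered 48 and 23 after quantile normalization, 70 and 49 after normexp, 21 and 7 with no filter on dim probes, 61 and 24 with a variance trend, 88 and 45 with slide as a random block (correlation -0.089), 0 and 0 with slide as a fixed block (1 ANP array), 25 and 10 with a 2-fold minimum and 13 and 8 with only the day's own arrays. At day 28 (530 and 312) normexp gave 670 and 577, the random slide block 1098 and 758, the 2-fold minimum 102 and 73, and the day's own arrays 238 and 227. Genes different between vehicle groups (1327) numbered 2204 with the random slide block, 452 with the 2-fold minimum and 721 with only those groups. The random block kept all 57 and 842 calls among the 133 and 1856 it gave, with a correlation below 0. Vehicle and ANP arrays of day 28 lay on separate slides, so this block cannot test the slide there. The share of higher genes among calls went from 75.4% to 58.8% at day 14 with normexp and from 62.9% to 76.0% at day 28 with scaling to the array median, and no scaling moved the median of all genes by over 0.1. The authors' value table, the mean of all probes and the filter on all 12 arrays kept the counts within 1.5 times. In the pools of day 7, genes at least 2-fold higher and lower (282 and 343) numbered 146 and 174 when well above background on both arrays.

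With the glomerular score as a covariate no gene passed at day 14, at day 28 (0 higher, 0 lower in each) or between vehicle groups (0). The median SE rose from 0.135 to 0.237 at day 28, because the score differs between groups, while the median size of the 842 called ratios went from 0.63 to 0.544 and 841 kept their sign; 1358 genes had an unadjusted p under 0.05. At day 14 the median size of the 57 called ratios did not shrink (1.14 to 1.23, all 57 of the same sign) and the median SE rose to 0.204. Between vehicle groups it shrank from 0.778 to 0.36, 1149 of 1327 kept their sign and the median SE rose to 0.312. Asns went from 3.47 ± 0.30 to 3.72 ± 0.56, Gstm1 from 4.32 ± 0.73 to 6.32 ± 1.13 and Cldn14 from 2.73 ± 0.65 to 0.383 ± 0.80, and the NRF2 median from 1.08 to 1.42. Among called lists, signs turned for convoluted proximal tubule markers (0.296 at day 14, 0.474 at day 28) and lymphocyte markers at day 28 (0.0809). Among named genes past the threshold they turned between vehicle groups for Klk1 (-0.104), Klk1c2 (-0.329) and Cldn14 (0.361). Glomerular markers stood at 0.00537 at day 14, but the score is the mean of this same list, so a value near 0 was fixed in advance. Heat shock genes at day 14 turned to -0.0189 without vehicle replicate 3 and were at 0.281 without vehicle replicate 1.

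Leaving out 1 array gave 0 to 69 genes higher and 1 to 26 lower at day 14, 144 to 554 higher and 60 to 421 lower at day 28, and 430 to 1598 different between vehicle groups. At day 14 the counts were 14 and 10 without ANP replicate 1, 3 and 4 without ANP replicate 2, 0 and 1 without ANP replicate 3, 2 and 1 without vehicle replicate 2 and 28 and 26 without vehicle replicate 3, and, through the shared spread, 26 and 9 without vehicle day 28 replicate 3 and 69 and 24 without ANP day 28 replicate 1. At day 28 they were 144 and 68, 148 and 60, and 296 and 177 without vehicle replicates 1, 2 and 3, and 344 and 208, and 180 and 117 without ANP replicates 1 and 2. The vehicle total was 583 and 586 without vehicle day 14 replicates 2 and 3, and 513 and 430 without vehicle day 28 replicates 1 and 2. Genes with a larger log2 ratio at day 28 than at day 14 numbered 0 to 2, the 2 without ANP day 14 replicate 1, and those with a smaller ratio 0 to 1, the 1 without vehicle day 14 replicate 1. Fewer arrays also leave fewer degrees of freedom.

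Whether the replicate numbers pair the samples stays open. Deviations of like-numbered arrays correlated at 0.128, 0.0693 and 0.144 at day 14 and at -0.0676, -0.0436 and 0.112 at day 28. Of the 6 ANP arrays, 4 correlated best with the vehicle array of their own number, among them all those of day 14. With a replicate block 3 genes were higher and 4 lower at day 14, and 286 higher and 211 lower at day 28; the block takes up the day, so the vehicle groups have no value there. Probes near background may limit the small folds, which was not tested, and 64.75% to 69.6% of probes were well above it.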

Other observations

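Distal convoluted and connecting tubule genes, from a list written after the other lists had been seen, had a median log2 ratio of -0.916 with ANP at day 28, where Slc8a1 (-1.86) and Egfl6 (-0.87) fell, 8 of 10 did not pass, and Slc12a3, the thiazide-sensitive cotransporter, was at -1.47. Between the vehicle groups 7 of 10 were higher at day 28, among them Slc12a3 (2.56) and calbindin Calb1 (2.35). On the vehicle arrays of day 14, Klk1 stood at 4.54, 3.09 and 0.25 on the log2 scale, against 6.18 to 6.80 on those of day 28.

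Some day 28 differences lay partly on the vehicle side. Cldn14 had a mean of -2.81 in vehicle and -0.08 in ANP at day 28, and of 0.20 in vehicle at day 14. Slc22a7 had means of 1.43 and 3.11 at day 28 and of 2.57 in vehicle at day 14. Asns showed no such pattern, with vehicle means of -0.49 at day 14 and -0.81 at day 28 against 2.66 with ANP at day 28.

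Some genes differed among the ANP animals of day 28 and others did not. Akr1b8 stood at 2.62 in replicate 1 and at 6.12 or more in replicates 2 and 3, Gstm1 at 2.66, 6.10 and 5.39, and Nqo1 at 0.40, 2.12 and 2.61, while Gclm, an NRF2 target as well, stood at -0.23, -0.08 and -0.11. Hmox1 on the vehicle arrays of day 28 was at -1.69, 1.19 and -2.03, so that replicate 2 overlapped the ANP arrays.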
